A study of Oryza sativa Japonica Group with 3 samples.

How the data were processed

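Nuclei of dissected rice pistils (Oryza sativa ssp. japonica cultivar Nipponbare, heading stage, wild type) were stained with propidium iodide and sorted by DNA content, per the labels' protocols. Both 2N libraries (replicate 1 and replicate 2, called diploid and sporophytic in the series design) were made with the standard 10x Genomics kit and the 1N library (replicate 1, called haploid and gametophytic) with the low-throughput kit, per the labels' protocols. Ploidy gate, kit and sequencing depth therefore change together between the groups. The labels name separate replicates but do not say that they came from separate plants, so p-values measure only the spread between these libraries, which may be technical. The bulk RNA-seq that the series design mentions was not analysed here.

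The deposited matrices hold raw UMI counts per gene and barcode, and the authors made them with Cell Ranger 6.1.2 (file headers and submitters' processing notes) on genome build IRGSP-1.0 (submitters' processing notes). The annotation release, the intron setting and the cell-calling setting are not given in the sources used here. UMI counts were whole numbers and were not normalised by the authors. No genome of that build was used, so genes are given by the symbols and identifiers of the deposited feature list and no coordinates are printed. The feature list pairs 9826 features with a symbol that differs from the identifier.

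The barcodes numbered 6784, 8232 and 3823 in 2N replicate 1, 2N replicate 2 and 1N replicate 1, with 7697379, 3638943 and 1000078 UMIs and medians of 1021, 376 and 225 UMIs per barcode. Nuclei were kept with at least 200 genes and at most 10% organelle-encoded UMIs. The gene minimum removed 6, 1782 and 1933 barcodes and the organelle limit 13, 11 and 1. Scrublet, run per library in scanpy 1.11.5, called 0, 0 and 6 doublets. It has not worked on these libraries, so doublets remain in the data. The kept nuclei numbered 6765, 6439 and 1883, or 99.7%, 78.2% and 49.3% of the barcodes. Their median depths were 1021, 441 and 334 UMIs.

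The 2N nuclei of both libraries were clustered together. UMIs were scaled to 1000 per nucleus and logged, 2000 variable genes were taken as those with the largest residual of log variance on a quadratic in log mean, with ranks averaged over libraries, and genes were centred and scaled within each library. Then followed 30 principal components, 15 exact nearest neighbours with Jaccard weights, and Leiden clustering at resolution 0.8 (leidenalg 0.10.2). The 1465 genes of the functional and marker lists, and organelle and ribosomal RNA genes, were left out of the variable genes, so that list genes did not themselves set the clusters. Variable genes expressed together with them still could. Clusters with under 20 nuclei in either library were dropped (1 nucleus). The 1N library was clustered alone in the same way, and all 3 libraries were clustered together as an alternative.

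The marker and functional gene lists, the named-gene rule, the tests and their alternatives were fixed before the data were examined. Lists were filled by matching gene symbols of the feature list afterwards, and lists that symbols could not fill were left out (NLR genes, SPT and HEC bHLH genes, the ECA1 family, nuclear pore genes). OsMADS3, fixed by its identifier Os01g0201700, appears under its symbol RAG, and 1 gene with the same symbol as the tapetum marker OSC6 but another product was left out. The list of LEA and dehydrin genes was added after the most abundant genes had been seen. The rule that names clusters was also set after the data had been seen: at least 3 markers of a list, and at least 1 in 3 of its markers detected at 20 CPM in any cluster, had to lie over 2-fold above the mean of the other clusters and at 20 CPM or more. Where several lists met the rule, the one with the largest share of markers gave the name. A cluster whose 10 genes with the largest fold held more markers of another list than of its own stayed unnamed. The lists used for naming were carpel wall, ovule, epidermis, vascular, green parenchyma and meristem. The female gametophyte list was left out of naming after it had tagged clusters 16 and 17. The stigma, pollen, tapetum and endosperm lists gave no names either, though their markers could leave a cluster unnamed. The stigma and style list was filled from lipid transfer, fasciclin-like, arabinogalactan, YUCCA and expansin B families, without SHI or NGATHA genes. Its lipid transfer genes are also in the cuticle list, so it is not a list of those tissues alone. Markers drawn in the heat map were picked for display.

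For 1N against 2N, UMI counts of all kept nuclei were summed per library and tested with edgeR 4.0.16 (filterByExpr, TMM, glmQLFit and glmQLFTest, two-sided, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. With 3 libraries the fit has 1 residual degree of freedom, and the lone 1N library is assumed to vary as the 2N libraries do. The prior degrees of freedom, estimated across genes, were 11.7, so significance rests mostly on that prior. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and their medians were set against 10000 random lists matched on mean expression. For 1N against 2N the estimated correlation rests on 1 residual degree of freedom, so that version of the test can hardly call a list. For a gene at 0 UMIs in the 1N library, the bound on its change uses a floor of 3 counts in that library (3.50 normalised CPM). For 1 to 3 UMIs, the ratio carries an exact 95% binomial interval on the counts, which covers counting error only.

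For 2N clusters, UMIs were summed per library and cluster (38 sums, 19 clusters) and each cluster was tested against the mean of the others with library as a block (18 residual degrees of freedom, 11833 genes). Lists that resemble naming markers were skipped and naming markers were removed from the other lists, which left 25 lists per cluster and 475 cluster-list pairs. Shares of nuclei with a UMI were computed after thinning every nucleus to 250 UMIs, which left out 0, 342 and 218 shallower nuclei of 2N replicate 1, 2N replicate 2 and 1N replicate 1. The leading and background clusters set beside them were chosen after levels had been seen. Shares carry exact (Clopper-Pearson) 95% intervals.

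Genes named for 1N against 2N are the 10 higher and the 10 lower with the largest fold change among called genes with a symbol and at least 50 CPM in the 1N library or in both 2N libraries. One of the higher genes is not reported here. Added to them are the 3 members with the smallest p of each list that camera called or that had at least 3 called members. For clusters, up to 3 members with the smallest p per called list qualify. Clock genes were chosen after CCA1 had been seen and before their own values, and all other genes after values were seen.

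The tests were tried on simulated counts with 200 changed genes. For 1N against 2N (20938 genes), 2% of genes changed 2-fold and 51% of those changed 4-fold were recovered, and 1 of 20738 unchanged genes was called. Simulated counts cannot test whether the lone 1N library varies as the 2N libraries do, or whether kit or gate alters counts. The rate of false calls between the real 1N and 2N libraries therefore stays unknown. For a 2N cluster against the others (9692 genes), 31% and 78% were recovered and 6 of 9496 unchanged genes were called.

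Alternatives were RLE size factors, library size only, DESeq2 1.42.0, other count filters, all barcodes, nuclei with at least 400 genes, doublet calls kept, organelle-encoded and the 10 most abundant genes left out of library sizes, thinning of library sums to 711046 UMIs, other clustering settings, no block for library, and leaving out each 2N library. Taking the same number of nuclei per joint cluster (1026 per library) and leaving out the top 5% of doublet scores were added after the data had been seen.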

Results

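Single-nucleus RNA-seq was available for 3 libraries of rice pistils at the heading stage. The 2N sorting gate gave 2 of them, called diploid and sporophytic in the series design. The 1N gate gave 1, called haploid and gametophytic. The series design contrasts expression in 1N and 2N nuclei, and the 2N libraries also show how expression differs among pistil cell groups. After filtering, 2N replicate 1 held 6765 nuclei with 7686160 UMIs, 2N replicate 2 held 6439 nuclei with 3314291 UMIs, and 1N replicate 1 held 1883 nuclei with 711046 UMIs. Organelle-encoded UMIs made up 0.395%, 0.527% and 1.01% of the UMIs of these nuclei.

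Library sums of the 2N replicates were close to each other. Across 20684 genes, log2 CPM values of 2N replicate 1 and 2N replicate 2 had a Pearson correlation of 0.939 and a Spearman correlation of 0.939, and 8.65% of genes differed over 2-fold. The 1N library had Pearson correlations of 0.707 and 0.705 with 2N replicates 1 and 2, and 37.2% and 39.6% of genes differed over 2-fold. Genes are not independent replicates, so these values describe the libraries only. The 1N library held 711046 UMIs against 7686160 and 3314291, so counting noise lowers its correlations and adds 2-fold differences. How much of the gap it makes up was not tested.

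The 2N nuclei formed 19 clusters, of which 12 carried a name from marker genes. Genes of floral organ identity separated several of them, as the heat map of marker genes shows. DL (Os03g0215200), a YABBY gene of carpel identity, was detected after thinning in 28.4% (22.0 to 35.5%) of cluster 16 nuclei in 2N replicate 1 and in 0 of 113 nuclei of cluster 15, with median depths of 1138 and 1040 UMIs. OsMADS13 (Os12g0207000), an ovule identity MADS gene, was detected in 46.8% (37.8 to 55.9%) of nuclei of the unnamed cluster 17 and in 0.805% (0.220 to 2.05%) of cluster 3, with median depths of 932.5 and 1211 UMIs. ONI1 (Os03g0181500), an epidermal fatty acid elongation gene, was detected in 38.0% (33.2 to 42.9%) of cluster 8 and 0.532% (0.0645 to 1.91%) of cluster 10, at median depths of 1050 and 845 UMIs. In 2N replicate 2 the same leading clusters held 25.0%, 42.7% and 13.3% of nuclei with DL, OsMADS13 and ONI1. The meristem gene FON1 was among the leading genes of cluster 19. Rab16A and RAB16B, dehydrin genes induced by drying, were among the leading genes of green parenchyma-like cluster 13. OsHAK27, OsENOD93, OsNRT1.5B and OsYAB7 were among those of unnamed clusters 4, 9, 11 and 17.

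**Figure D1:**
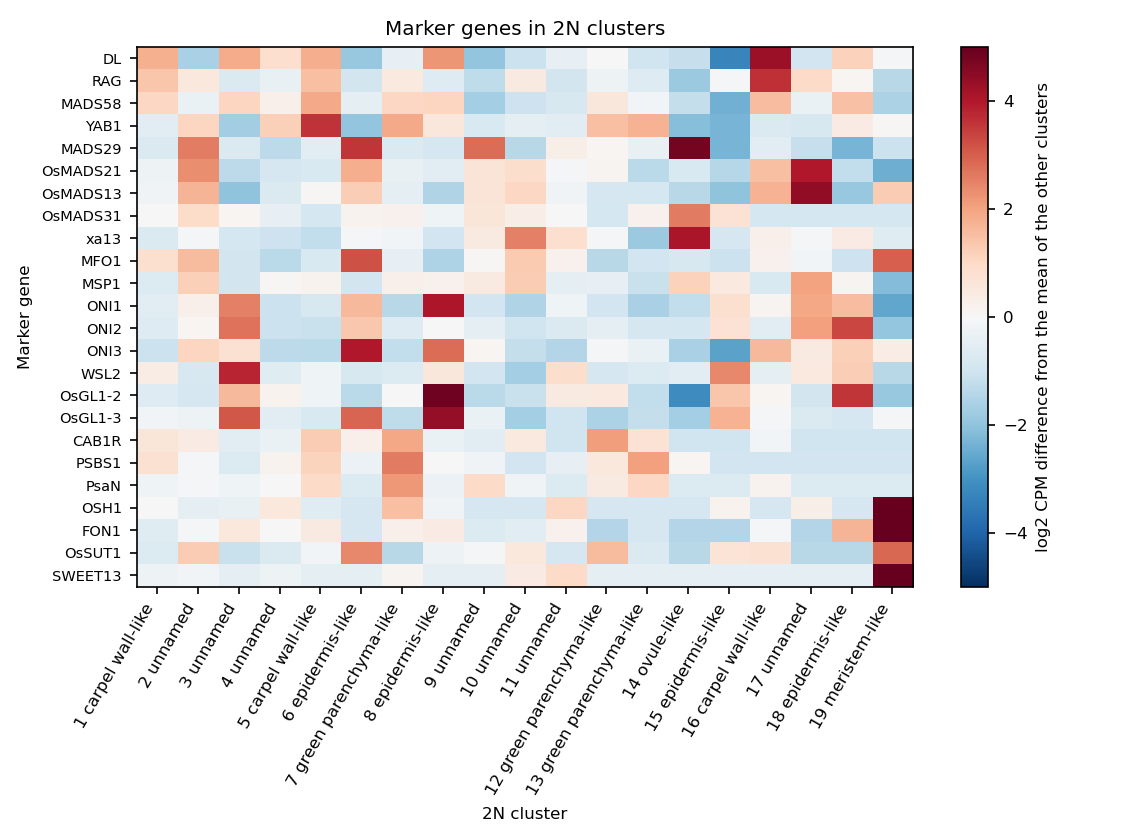
Log2 difference in CPM (5 CPM added) between each 2N cluster and the mean of the other clusters, for selected marker genes (vertical axis) and the 19 clusters (horizontal axis). MADS29 and xa13 stood highest in ovule-like cluster 14, OsMADS13 in unnamed cluster 17, and OSH1, FON1 and SWEET13 in meristem-like cluster 19.

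Cluster 19 also met the naming rule for ovule and vascular markers, and each cluster took only the name of the list with the largest share of its markers. Clusters 2 and 10 met the rule for ovule and cluster 3 for epidermis, but they stay unnamed because their leading genes held more markers of another list. These were OsAGP9, OsAGP17 and OsLTP1.3 of the stigma and style list in cluster 2, OsLTPd5 of that list in cluster 10, and WDA1 of the tapetum list in cluster 3. Clusters 2, 3 and 10 held 8.16%, 7.35% and 5.56% of nuclei in 2N replicate 1 and 10.996%, 11.46% and 4.33% in 2N replicate 2. Carpel wall-like clusters held 23.6% and 17.95% of nuclei in 2N replicates 1 and 2, but 13.5% and 3.62% with 50 principal components, so clusters are described by number. As a ratio, the replicates differed most in green parenchyma-like cluster 12, with 0.976% (0.755 to 1.24%) of nuclei in 2N replicate 1 and 7.31% (6.69 to 7.98%) in 2N replicate 2. In percentage points they differed most in carpel wall-like cluster 5, with 11.99% (11.2 to 12.8%) and 3.73% (3.28 to 4.22%). The names rest on a rule set after the data were seen, and no test was made on shares.

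**Figure D2:**
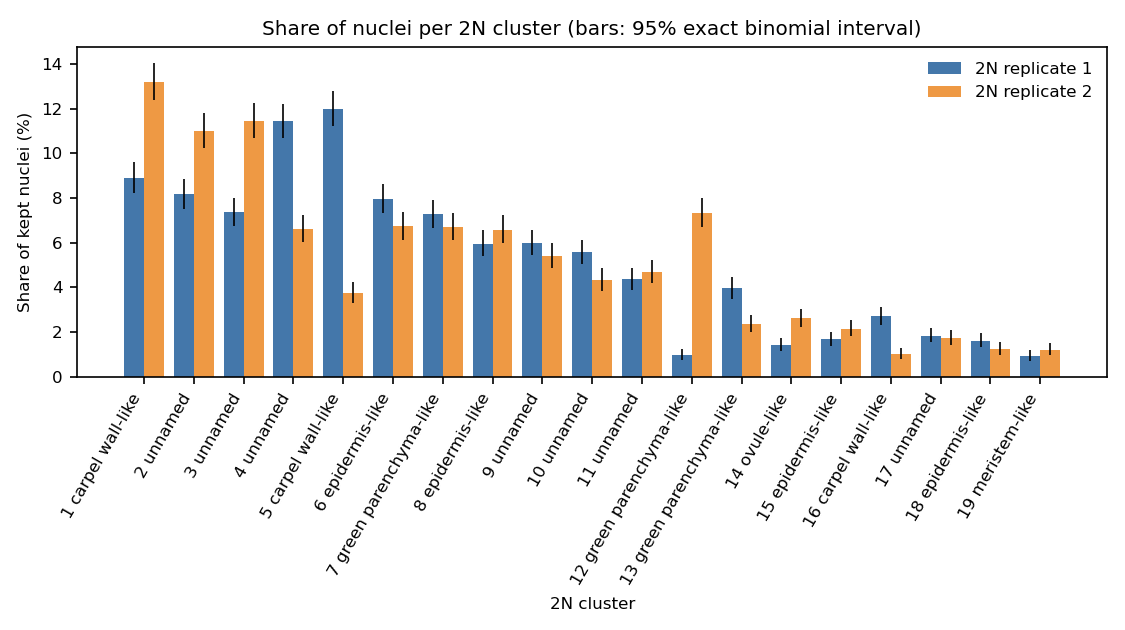
Share of kept nuclei (vertical axis, %) in each 2N cluster (horizontal axis) for 2N replicate 1 and 2N replicate 2, with exact 95% binomial intervals as bars. Clusters 5 and 12 differ most between the replicates, with 11.99% against 3.73% and 0.976% against 7.31%.

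The next comparison asked which functional gene groups differ among 2N cell groups. WRKY transcription factor genes, many of which act in stress and defence, were higher in epidermis-like cluster 8 and in unnamed cluster 11. In cluster 8 the WRKY median log2 fold change was 1.49 and 23 of 41 genes were called higher (camera adjusted p = 1.19e-11, and adjusted p = 0.00129 with an estimated correlation). OsWRKY113 (Os06g0158100) reached 954 and 580 CPM in cluster 8 of 2N replicates 1 and 2, against 79.3 and 47.6 CPM in the other clusters (edgeR log2 fold change 4.95, SE 0.20, adjusted p = 3.45e-34). In cluster 11 the WRKY median was 1.36 and 22 of 41 genes were called higher (camera adjusted p = 8.42e-06, and adjusted p = 0.0173 with an estimated correlation). Adjusted over the list alone, 25 and 24 WRKY genes were higher in these clusters.

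Cuticle, wax and lipid transfer genes, which build the plant surface layer, were higher in epidermis-like clusters 8 and 18. Their median log2 fold change was 1.54 in cluster 8, with 25 of 41 genes higher, and 0.73 in cluster 18, with 15 of 41 higher. Adjusted over the list alone, 26 and 16 were higher, and 1 was lower in cluster 8. The camera adjusted p was 4.37e-19 and 9.26e-16, and adjusted p = 0.00459 and 0.00221 with an estimated correlation. In cluster 18, OsCER2 (Os04g0611200), a wax gene, reached 201 and 301 CPM against 15.2 and 17.4 CPM elsewhere (edgeR log2 fold change 5.06, SE 0.47, adjusted p = 7.18e-14). Epidermis markers that named the clusters were taken out of this list first. The epidermis name of both clusters rests partly on genes of the same surface layer, such as OsGL1-2 and ONI1. Higher levels of related genes there are therefore not independent of the name.

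Starch synthesis genes were higher in green parenchyma-like cluster 7, with a median log2 fold change of 1.04 and 8 of 15 genes higher (10 adjusted over the list alone). The camera adjusted p was 5.07e-05, and adjusted p = 0.00760 with an estimated correlation. The granule-bound starch synthase gene GBSSII (Os07g0412100) reached 280 and 177 CPM there, against 60.7 and 33.1 CPM in the other clusters (edgeR log2 fold change 3.03, SE 0.27, adjusted p = 3.76e-14). In all, camera called 67 of the 475 pairs, 44 higher and 23 lower, and only the 5 pairs just described were also called with an estimated correlation.

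Some small RNA pathway genes were higher in unnamed cluster 11. The Dicer-like genes OsDCL2a (Os03g0583900) and OsDCL2b (Os09g0315100) make small RNAs, and RDR1 (Os02g0736200) is an RNA-dependent RNA polymerase. OsDCL2a reached 2404 and 1986 CPM in cluster 11 of 2N replicates 1 and 2, against 314 and 334 CPM elsewhere (edgeR log2 fold change 3.36, SE 0.18, adjusted p = 4.85e-26). OsDCL2b reached 636 and 987 CPM against 61.2 and 94.0 CPM, and RDR1 420 and 516 CPM against 76.2 and 127 CPM. Of 23 small RNA pathway genes, 7 were higher there (7 adjusted over the list alone), and the list median was 0.19 (camera adjusted p = 0.000508, and adjusted p = 0.181 with an estimated correlation).

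Hormone lists were called in 14 of the 19 clusters, each tested against the mean of all other clusters and not against each other. Jasmonate genes were higher in clusters 4, 5, 11 and 13 and lower in clusters 2, 6 and 14, and abscisic acid genes were higher in clusters 1 and 13 and lower in clusters 6, 9 and 14. Cytokinin genes were higher in clusters 1, 10 and 16, gibberellin genes in clusters 1, 5, 7 and 12, and auxin response genes in clusters 1 and 15. Auxin response genes were lower in cluster 6 and ethylene genes in cluster 2. With an estimated correlation, 0 of these 23 pairs were called. The examples below come from the carpel wall-like clusters. In cluster 16 the type-A cytokinin response regulator RR10 (Os12g0139400) reached 196 and 97.9 CPM, against 5.76 and 4.89 CPM elsewhere. Another, OSRR9 (Os11g0143300), reached 339 and 97.9 CPM there, against 9.38 and 20.8 CPM. In 2N replicate 2 this cluster held 66 nuclei and levels moved in steps of 24.5 CPM, so 97.9 CPM is only a few UMIs. Of 20 cytokinin genes, 10 were higher in cluster 16 (11, with 1 lower, adjusted over the list alone), with a median of 1.32 (camera adjusted p = 0.000322, and adjusted p = 0.200 with an estimated correlation). In cluster 5 the gibberellin biosynthesis genes GA20OX4 (Os05g0421900) and D18 (Os01g0177400) had edgeR log2 fold changes of 4.15 (SE 0.31, adjusted p = 6.23e-18) and 3.58 (SE 0.31, adjusted p = 3.78e-15). Of 10 gibberellin genes, 6 were higher there (7 adjusted over the list alone), with a median of 1.35 (camera adjusted p = 0.00135, and adjusted p = 0.190 with an estimated correlation). In cluster 1, 12 of 16 abscisic acid genes were higher (13 adjusted over the list alone), led by the kinase gene SAPK5, with a median of 0.83 (camera adjusted p = 2.34e-08, and adjusted p = 0.0600 with an estimated correlation).

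Replication genes were higher in epidermis-like cluster 6, which also met the rule for ovule markers. The helicase gene OsMCM5 (Os02g0797400) reached 46.9 and 95.8 CPM there, against 15.05 and 10.9 CPM elsewhere (edgeR log2 fold change 2.67, SE 0.47, adjusted p = 9.67e-06). Of 14 DNA replication genes, 8 were higher (8 adjusted over the list alone), with a median of 1.26 (camera adjusted p = 0.00372, and adjusted p = 0.0600 with an estimated correlation). Unnamed cluster 2 had a median of 0.86 for this list, with 4 of 14 genes higher (7 adjusted over the list alone, camera adjusted p = 0.0156, and adjusted p = 0.138 with an estimated correlation). The DNA methylation genes OsDDM1a and MET1B were higher in cluster 2 by log2 fold changes of 2.59 (SE 0.46) and 2.11 (SE 0.45), with edgeR adjusted p of 6.17e-05 and 0.000872. In ovule-like cluster 14, 3 of 5 polycomb genes were higher (4 adjusted over the list alone, median 0.94, camera adjusted p = 0.0224, and adjusted p = 0.252 with an estimated correlation).

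**Figure D3:**
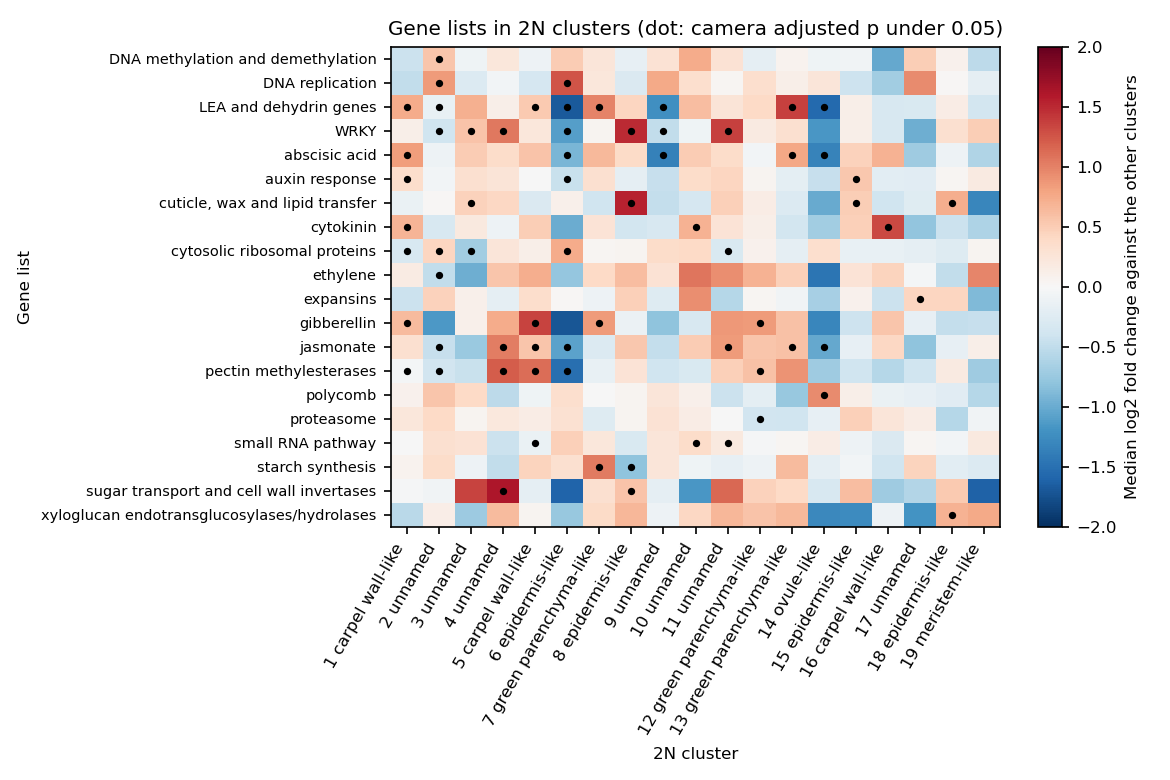
Median log2 fold change of each gene list with a call (vertical axis) in each 2N cluster against the other clusters (horizontal axis), with a dot where the camera test at the preset correlation was called. The 67 dots include WRKY and cuticle genes in cluster 8 (medians 1.49 and 1.54) and starch synthesis genes in cluster 7 (median 1.04).

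The main comparison asked how the 1N library differs from the 2N libraries. The clock transcription factor gene CCA1 (Os08g0157600) stood at 1915 CPM in the 1N library, against 10.1 and 13.3 CPM in 2N replicates 1 and 2 (edgeR log2 fold change 6.95, SE 0.44, adjusted p = 5.22e-06). The PLETHORA-type gene OsPLT8 (Os07g0124700) stood at 259 CPM against 1.95 and 0.603 CPM (log2 fold change 7.003, SE 0.47, edgeR adjusted p = 7.14e-06). OsTPS14 (Os03g0428200) had 37 UMIs in the 1N library and 1 over both 2N libraries, a ratio of 428 (counting interval 72.2 to 17356). The meiotic mismatch-repair homologue OsMSH4 (Os07g0486000) stood at 170 CPM against 5.59 and 7.54 CPM. Genes of plastids and light harvesting were also among the 10 named higher genes: OsPorA, OsSIG5, LYL1 and ASCAB9-A, with log2 fold changes between 4.09 and 4.28. LYL1 (Os02g0744900) rose from 6.38 and 3.32 CPM to 125 CPM. OsPorA (Os04g0678700) had 22 and 2 UMIs in 2N replicates 1 and 2 and 37 in the 1N library. Its log2 CPM difference was 4.70 without 2N replicate 1 and 3.56 without 2N replicate 2. Piz, also in that group, had a log2 fold change of 4.69.

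All 10 genes named as lower had 0 UMIs in the 1N library. The transcription factor genes OsbHLH006 (Os04g0301500) and DERF3 (Os08g0474000) were at least 109-fold and at least 78.5-fold lower. C10501, FCO9, the uclacyanin gene OsUCL29 and the potassium transporter gene OsHAK27 were at least 76.0-fold, 70.3-fold, 69.0-fold and 66.7-fold lower. Against 2N replicate 2 alone, the bounds for C10501 and OsHAK27 came to 35.5-fold and 41.9-fold. The gibberellin-inactivating OsGA2ox9 and the flagellin receptor Os-FLS2 were each at least 57.4-fold lower, wsi76 at least 45.2-fold and OsRLCK253 (Os08g0374600) at least 39.6-fold. WRKY71 (Os02g0181300), with 2 UMIs in the 1N library and 5556 over both 2N libraries, was 240-fold lower (counting interval 66.5 to 1984). The sugar transporter gene OsMST6 (Os07g0559700) was 289-fold lower (79.9 to 2385), from 748 and 280 CPM in 2N replicates 1 and 2, and 133-fold lower against 2N replicate 2 alone.

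Of 21601 genes tested, edgeR called 615 higher and 2200 lower in the 1N library, and 5671 had an unadjusted p under 0.05. The direction of the split depended on scaling. Higher genes made up 21.8% of calls with TMM, where the median gene had a log2 fold change of -0.10, and 52.3% with library size only (1881 higher, 1714 lower), where the median gene had 0.32. After thinning to equal totals no gene was called by edgeR (0 higher, 0 lower, 3096 with an unadjusted p under 0.05). All 2668 main calls still tested kept their sign there, and the estimated prior degrees of freedom fell from 11.7 to 1.17. DESeq2 called 213 higher and 1421 lower. There is 1 library in the 1N group, so no 1N replicate checks these differences, and gate, kit and depth cannot be told apart.

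LEA and dehydrin genes, whose proteins protect cells during drying, had the lowest median of the called lists. For all lists between 1N and 2N the estimated correlation rests on 1 residual degree of freedom, so the test with it could hardly call any. LIP9 (Os02g0669100) stood at 2010 and 1827 CPM in 2N replicates 1 and 2 and at 160 CPM in the unreplicated 1N library (edgeR log2 fold change -3.999, SE 0.51, adjusted p = 0.000376). OsLEA14 (Os01g0705200) stood at 1458, 1166 and 63.3 CPM. Of 19 measured genes of this list, added after abundant genes had been seen, 15 were lower (17 adjusted over the list alone). The median was -4.53, or -3.05 with 5 genes at 0 UMIs set at their bound (camera adjusted p = 4.70e-14, and adjusted p = 0.807 with an estimated correlation).

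WRKY, abscisic acid, jasmonate and gibberellin genes were also lower in the unreplicated 1N library. Of 57 WRKY genes 24 were lower (29 lower and 1 higher adjusted over the list alone), with a median of -2.26, or -1.75 at the bound (camera adjusted p = 2.88e-09, and adjusted p = 0.807 with an estimated correlation). Of 26 abscisic acid genes 12 were lower and 1 higher (14 and 1 adjusted over the list alone), with a median of -2.17, or -1.65 at the bound (camera adjusted p = 4.84e-05, and adjusted p = 0.807 with an estimated correlation). OsPP2C30, a phosphatase gene of the abscisic acid pathway, fell from 764 and 482 CPM to 54.8 CPM. Of 23 jasmonate genes 11 were lower (13 adjusted over the list alone), with a median of -1.78 (camera adjusted p = 1.52e-06, and adjusted p = 0.807 with an estimated correlation). As log2 CPM differences the jasmonate median was -1.49 without 2N replicate 1 and -1.18 without 2N replicate 2. OsJAZ2, a jasmonate repressor gene, had 3 UMIs in the 1N library and was 46.6-fold lower (counting interval 15.9 to 226), or 30.2-fold against 2N replicate 2 alone. Of 12 gibberellin genes 4 were lower and 1 higher (7 and 1 adjusted over the list alone, median -1.94, or -1.44 at the bound, camera adjusted p = 0.00934, and adjusted p = 0.807 with an estimated correlation), but this list was not called with the same number of nuclei per joint cluster (median -1.60). Pectin methylesterase genes had a median of -0.83, with 7 of 17 lower and 2 higher (8 and 2 adjusted over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.807 with an estimated correlation). These 6 lists also had negative medians with library size only, between -4.11 and -0.41.

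Nuclear photosynthesis genes were the clearest higher list. CAB1R (Os09g0346500), a light-harvesting protein gene, stood at 207 CPM in the unreplicated 1N library, against 6.24 and 12.97 CPM (edgeR log2 fold change 4.07, SE 0.42, adjusted p = 0.000142). Of 32 photosynthesis genes 11 were higher (15 adjusted over the list alone), with a median of 1.23 (camera adjusted p = 1.11e-13, and adjusted p = 0.807 with an estimated correlation). The overlapping green parenchyma marker list had a median of 1.28, with 11 of 33 higher (15 adjusted over the list alone) and the same camera values. Organelle-encoded genes had a median of 0.64, with 4 of 69 higher (0 adjusted over the list alone, camera adjusted p = 2.02e-05, and adjusted p = 0.807 with an estimated correlation).

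Small developmental lists were higher as well in this 1 library. The YABBY genes OsYAB7 and OsYAB6 had log2 fold changes of 1.62 (SE 0.34) and 1.38 (SE 0.37), with edgeR adjusted p of 0.00780 and 0.0271. YABBY (4 genes, 2 higher), auxin transport (8 genes, 2 higher), KNOX (5 genes, 1 higher) and meristem markers (6 genes, 1 higher) had medians of 1.24, 1.32, 1.75 and 1.66. Adjusted over the list alone, 3, 2, 2 and 3 were higher. All 5 KNOX genes are also meristem markers and OSH1 is the gene called in both, so these 2 lists are 1 result. With the same number of nuclei per joint cluster the meristem list was not called (median 0.79). Their camera adjusted p was 0.00560, 0.0101, 0.0152 and 0.00934, and adjusted p = 0.807 with an estimated correlation. Cytosolic ribosomal protein genes had a median of 0.24, with 1 of 75 higher (0 adjusted over the list alone), and -0.01 without 2N replicate 2 (camera adjusted p = 0.0101, and adjusted p = 0.870 with an estimated correlation).

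**Figure D4:**
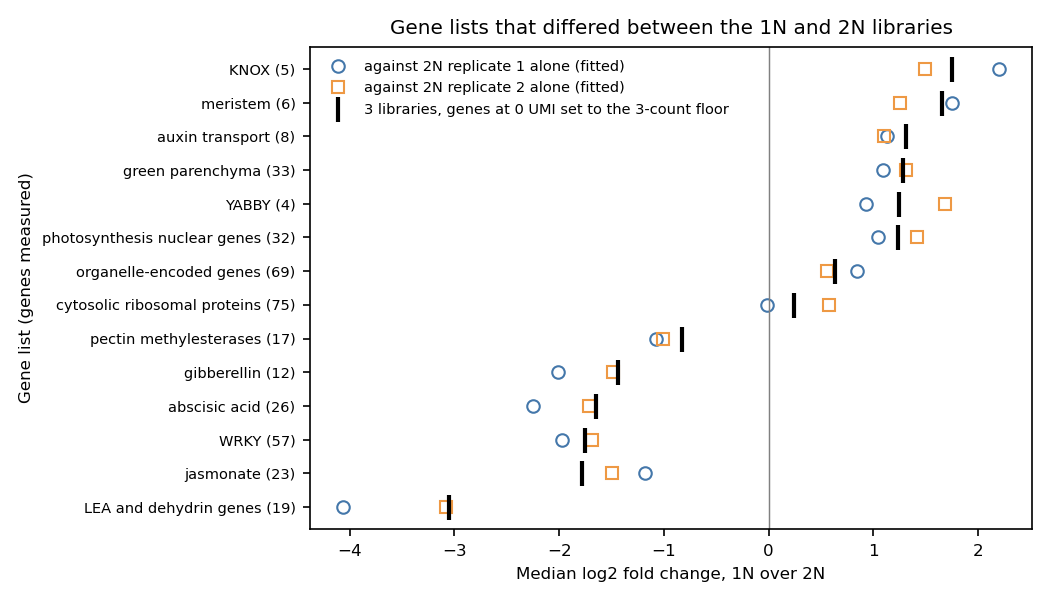
Median log2 fold change of the 14 called gene lists (vertical axis, genes measured in brackets) in the 1N library over the 2N libraries (horizontal axis). Bars use all 3 libraries with genes at 0 UMIs at their 3-count floor. Open circles and squares, labelled fitted in the legend, are medians of log2 CPM differences against 2N replicate 1 or 2N replicate 2 alone. LEA and dehydrin genes lie lowest at -3.05, and cytosolic ribosomal protein genes reach -0.01 against 2N replicate 1.

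The list of female gametophyte markers was not called. DEFL8 (Os03g0130300), a defensin-like gene, stood at 413 CPM against 129 and 136 CPM (edgeR log2 fold change 1.22, SE 0.35, adjusted p = 0.0389). It was detected after thinning in 8.17% (6.90 to 9.59%) of 1N nuclei, against 3.27% and 2.90% in the 2N libraries (11.2%, 10.4% and 5.36% unthinned). In 2N replicate 1 it was found in 12.6% (6.70 to 21.03%) of ovule-like cluster 14 and 1.83% (0.223 to 6.47%) of cluster 18, with median depths of 1100 and 1080 UMIs. Other female gametophyte markers went both ways. MEL1 had 1 UMI in the 1N library (1.41 CPM against 16.3 and 7.84 CPM), and OsWOX8 stood at 32.3 CPM against 61.8 and 50.7 CPM. OsAGO13 stood at 43.6 CPM against 14.96 and 13.3 CPM, and OsAGO14 at 290 CPM against 98.9 and 111 CPM. FIE1 and OsMADS78 had 0 UMIs in all 3 libraries. Of 9 female gametophyte genes measured, 1 was higher and 1 lower (4 and 2 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.298). The median was 0.59 with library size only and 1.08 over the 7 genes tested after thinning, and the list summed to 1425 CPM against 726 and 799 CPM. The identity genes MADS58, with 1661 CPM against 680 and 524 CPM, and OsMADS13, with 615 CPM against 231 and 198 CPM, were not called (edgeR adjusted p = 0.106 and 0.0696).

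Cell division and housekeeping lists were not called. Core histone, DNA replication, mitosis and dividing-nuclei genes had medians of 0.06, -0.08, 0.44 and 0.26, and proteasome genes 0.08. Mitosis genes summed to 336 CPM in the 1N library, below both 2N libraries (423 and 606 CPM), although their median was above 0. Carpel wall, ovule, epidermis and vascular markers had medians of 0.55, -0.39, -0.19 and -0.21 (camera adjusted p = 0.137, 0.819, 0.428 and 0.660). Ovule markers summed to 1049 CPM against 574 and 597 CPM, and their median was 0.02 with library size only, so the list has no clear direction. The stigma and style list had a median of -0.24, or -0.16 at the bound, with 4 of 76 higher and 17 lower (6 and 20 adjusted over the list alone, camera adjusted p = 0.428). It holds broad families such as lipid transfer and arabinogalactan genes, so these values do not describe stigma or style tissue as such. Pollen markers summed to 7.03 CPM in the 1N library, against 5.204 and 10.6 CPM in the 2N libraries. Endosperm and seed markers summed to 83.0 CPM against 102 and 99.9 CPM. Tapetum and anther wall markers summed to 707 CPM against 190 and 223 CPM, of which WDA1, a gene also found in unnamed cluster 3, made up 682, 158 and 179 CPM. Cluster 3 had 10 of 17 detected epidermis markers over 2-fold above the other clusters. The tapetum sum rests mostly on 1 gene, so it does not show tapetum or anther tissue. In 2N replicate 1, WDA1 was detected after thinning in 24.5% (20.8 to 28.6%) of cluster 3 and 0 of 267 nuclei of cluster 13, with median depths of 1211 and 1000 UMIs.

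The 1N library clustered alone gave 7 clusters, with 776, 487, 295, 154, 85, 46 and 40 nuclei. Cluster 4, with 8.18% (6.98 to 9.51%) of 1N nuclei, correlated best across 3707 genes with unnamed 2N cluster 3 (Pearson 0.428). Cluster 7, with 2.12% (1.52 to 2.88%), correlated best with meristem-like 2N cluster 19 (0.326), and cluster 3, with 15.7% (14.1 to 17.4%), with green parenchyma-like 2N cluster 7 (0.362). The largest, cluster 1 with 41.2% (39.0 to 43.5%), correlated best with unnamed 2N cluster 2 (0.345). Clusters 2, 5 and 6 correlated best with 2N clusters 1, 18 and 15 (0.220, 0.163 and 0.303). Several 1N clusters met the rule for markers of more than 1 tissue, and cluster 1 met it for green parenchyma, unlike its match, so 1N clusters are given by number only. Clusters 1 and 2 also met it for female gametophyte markers, with 3 of 7 detected markers each. OsAGO13 and ROS1D were in both. The 2N clusters 16 and 17 met it too, so meeting it does not single out the 1N library. When all 3 libraries were clustered together, joint cluster 1 held 67.4% of 1N nuclei, against 6.105% and 9.36% of 2N nuclei. With 1 library, such a cluster may be that library and not a cell type. Of 24 marker genes, 15 had a higher share of nuclei with a UMI in the 1N library than in both 2N libraries after thinning, and 10 unthinned. In 1N cluster 4, 9 of 16 detected epidermis markers lay over 2-fold above the other 1N clusters. In 1N cluster 7, 5 of 6 meristem markers did. These mark sporophyte tissues, so the 1N gate is not shown to hold only gametophyte nuclei.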

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

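Settings marked here as added (matched nuclei, doublet scores) were chosen after the results were seen, and the rest before the data were examined. The counts of genes differing between the 1N and 2N libraries (615 higher and 2200 lower, 2815 in all) moved most. With library size only there were 1881 higher. DESeq2 gave 213 higher and 1421 lower (1634), a minimum of 50 counts in each group 178 and 261 (439, of 3736 genes tested), nuclei with at least 400 genes 91 and 470 (561), and thinning to the shallowest library 0 and 0. The thinned fit had fewer genes and a prior of 1.17 degrees of freedom against 11.7. For the others the cause was not tested, apart from the fewer genes tested under the count minimum. RLE, no count filter, all barcodes, doublet calls kept, organelle-encoded and abundant genes left out, and both added settings stayed within 1.5 times. With matched nuclei the higher genes did so only at the edge of that range. The fits with no count filter and with matched nuclei had no finite prior degrees of freedom, so their calls rest on the fitted dispersion. Of 87 named genes, none reversed under any setting, and 44 and 32 moved without 2N replicate 1 and without 2N replicate 2. Part of these moves can come from the estimator, since values without a library are log2 CPM differences and not edgeR fits. Calls were lost for 14 with DESeq2, 12 with matched nuclei, 35 at 400 genes and 80 after thinning. Library size only and all barcodes each lost 5, and the minimum of 50 counts lost 4. With an estimated correlation, 0 of the 14 lists remained called between 1N and 2N. That test had 1 residual degree of freedom and could hardly call any list, so the loss decides little. Of the 67 cluster-list pairs, 5 remained called. Cytosolic ribosomal proteins reversed to -0.0102 without 2N replicate 2 (0.577 without 2N replicate 1), and the gibberellin and meristem lists were no longer called with matched nuclei. In cluster 12, OsGA2ox6 reversed to -0.378 without 2N replicate 2 (2.26 without 2N replicate 1), and in cluster 18 OsXTH1 reversed to -0.0729 without 2N replicate 1 (1.77 without 2N replicate 2). The cause was not tested. Clustering of the 1N library at resolution 1.2 gave 11 clusters instead of 7. Numbers of 2N clusters ranged from 13 to 25, and of the shares of the 5 names and of unnamed clusters, 3 to 5 moved under each clustering setting.

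No paired analysis was possible because the 1N group has a single library, so the groups share only 1 replicate number. Cluster contrasts kept library as a block. With no replicate block, 61 instead of 67 cluster-list pairs and 1085 list genes were called, and 18 of 201 named genes were no longer called.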

Other observations

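LEA and dehydrin genes also varied among 2N clusters. Rab16A (Os11g0454300), a dehydrin gene, reached 3279 and 498 CPM in green parenchyma-like cluster 13 of 2N replicates 1 and 2, against 595 and 175 CPM elsewhere. OsLEA24 reached 9163 and 8795 CPM in carpel wall-like cluster 1, and fell to 1511 and 1197 CPM in epidermis-like cluster 6. The list median was 1.37 in cluster 13 and -1.68 in cluster 6 (camera adjusted p = 5.55e-09 and 8.42e-06, and adjusted p = 0.174 and 0.200 with an estimated correlation). Os08g0543275, a gene without a symbol chosen after its values were seen, had 668 UMIs in the 1N library and 1 over both 2N libraries, a ratio of 7727 (counting interval 1382 to 305657).

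All tests below were chosen after the results were seen, except the tests of clock genes and of photosynthesis genes inside joint clusters, whose predictions were written before their values but after the patterns themselves had been seen. The rules that left the clock, free RNA and thinning tests undecided were tightened after their values were known. Joint clusters come from all 3 libraries clustered together, and 9 had at least 20 nuclei of each.

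LEA, abscisic acid, jasmonate and WRKY genes were low in the 1N library. A different mix of joint clusters would bring the pooled log2 ratio inside them above -0.5. Its median was -1.76 and all 9 lay below 0 (jasmonate alone, 8 of 9). Thinning library sums to equal totals does not change the expected CPM, so the median of -2.46 after it decides nothing about a shallower library. Depth, ploidy, kit, handling and collection remain open, so the pattern may be technical.

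CCA1 was high in the 1N library. A different mix of joint clusters would bring its log2 ratio inside them below 1, but the median was 6.64 and all 9 lay above 0. A different time of day at collection might explain it, since CCA1 peaks around dawn, and would bring 6 afternoon and evening clock genes below -1. Their median was -1.22, with OsPCL1 at -4.43 (1 UMI in the 1N library), FKF1 at -2.95, OsPRR1 at -1.34 and GI at -1.10. The median was -0.80 with library size only, where the median gene had 0.32. OsPRR59 and OsPRR95 went the other way (0.37 and 0.25). Among clock genes outside these 6, ELF4_chr.11 (19 UMIs in the 1N library), ELF4_chr.8 and ELF4_chr.3 changed by 2.26, 0.11 and -0.95. Time of day can therefore neither be excluded nor told apart from ploidy and kit. LHY changed by -0.48 (edgeR adjusted p = 0.528).

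Photosynthesis genes were high in the 1N library. A different mix of joint clusters would bring the log2 ratio inside them below 0.3, but the median was 2.46 and all 9 lay above 0. Free RNA in the suspension could raise these genes, and would give 1N clusters levels within 1.5 times of each other, where a ratio over 3 speaks against it. The highest and lowest clusters differed 5.54-fold, but the lowest had 10 UMIs, the bounds of both intervals differ 2.66-fold, and the ratio is 2.76 without that cluster, so free RNA cannot be told apart from expression here. Ploidy, kit and collection were not tested.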
